A study of Bos taurus with 8 samples.

How the data were processed

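Gene expression was measured in mammary gland tissue of 8 healthy lactating Holstein Friesian cows, 4 of high and 4 of low milk yield, on 8 Agilent bovine arrays of 2 colours (array design 023647). Per the labels, each array carried the RNA of 1 high-yield and 1 low-yield cow in the same lactation, and each of the 4 cow pairs was hybridised to 2 arrays with the dyes exchanged on the other array. Pairs 1 and 2 were in lactation II and pairs 3 and 4 in lactation IV, also per the labels. Total RNA came from 1 part of the gland, and 1000 ng was labelled with Cy3 or Cy5, per the labels' protocols. Per the file headers, pairs 1 and 2 lay on slide 1 in scan 1 and pairs 3 and 4 on slide 2 in scan 2. Lactation and slide therefore cannot be told apart, while both yields were on every slide.

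The deposited scanner files held intensity values, that is the mean brightness of each spot and the median brightness of its local background in each dye, extracted with Feature Extraction 10.10.1.1, per the file headers. They also held processed intensity values that the scanner software had corrected for background and dye, and a log10 ratio of red (Cy5) over green (Cy3), per the file headers. The authors also deposited normalised values for each array, whose making is not described in the labels. Its values were set against the scanner values of the same arrays and proved to be log2 ratios of high-yield over low-yield cow in every column, as the deposited values themselves show. Column medians of that log2 table lay between -0.0352 and 0.0235, so the authors' values were centred near 0. The slope of the authors' values on the scanner ratios lay between 0.700 and 0.913 for 6 of the columns, with correlations across probes of 0.919 to 0.978. For array 1 of pair 2 and array 1 of pair 3 it was 0.150 and 0.124, with correlations of 0.434 and 0.444, so those columns are strongly shrunken and the extent of the shrinkage is not stated by the authors.

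The ratios reported here were computed from the mean spot intensity and median local background with limma 3.58.1 in R 4.3.3, with data.table version 1.17.8 for reading and Python 3.11.15 for gene names and plots. Background was corrected with the normexp model and an offset of 50. The noise in that model was taken from the 153 negative control spots of each array (their median and median absolute deviation) in each dye. The usual saddle-point fit to all spots gave noise means of -477 in Cy3 for array 1 of pair 2, and of -1012 and -560 in Cy3 and Cy5 for array 1 of pair 3, far below the negative controls of those arrays. With that fit the SD of the log2 ratios of those arrays was 0.226 and 0.361, against 0.479 and 0.784 with the control-based noise. The control-based noise was therefore used for all arrays, a choice made after the files were read, from these parameters and not from the calls. The saddle-point fit was run as an alternative.

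Each array was normalised with within-array loess, with control spots at weight 0. Spots marked as outliers by the scanner software, between 6 and 118 per array, were given no value, and 0 spots were saturated. Spots of one probe were averaged, and the arrays of a pair were turned to high over low yield and averaged to 1 value per pair. Levels of single cows were rebuilt from the mean intensity and the log2 ratio of each array. Before this, the mean intensities of all arrays were brought to the same distribution. These levels, given as log2 intensity, are thus not measured intensities. A probe was kept if it was well above background in at least 6 of the 8 array channels of high-yield cows or of low-yield cows. This kept 29867 of 43653 probes, and between 22027 and 42482 probes per channel were well above background. The number of arrays limits the precision.

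Probes were named through their accession (25142 probes), gene number (1254), gene symbol (6727) or an older symbol (286), using a table of bovine genes of assembly ARS-UCD2.0, which served for names alone. For 519 probes the name in the file was kept, and 10619 probes had no gene symbol. In all, 33034 probes carried 1 of 16204 gene symbols. Positions are those of the probes on build HGSC Btau_3.1, per the file headers, and no exon or intron annotation of that build was used here. A gene was represented by its probe of highest mean intensity, chosen without regard to the ratios, which gave 12436 genes. Of 6767 genes with several kept probes, 2438 had at least 1 probe with the opposite sign.

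The replicate was the cow pair (n = 4), and the mean log2 ratio of the 4 pairs was tested against 0 with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment at 0.05. The difference between the effect of yield in lactation IV and in lactation II (2 pairs against 2) was tested in the same way. In 20 gene lists and 12 lists of cell type markers, limma's camera with a preset correlation of 0.01 between genes compared the members with all other genes, with adjustment over the 32 lists. Camera with a correlation estimated from the data and fry, which asks whether the members move one way on balance, were run beside it. Members of each list were also adjusted over the list alone. All adjusted p-values in the text come from these limma fits.

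The pairing was given by the arrays, since each pair shared its arrays. As a check, the levels of the 2 cows of a pair, as deviations from the mean of their yield group, correlated across probes at -0.165, 0.505, 0.117 and 0.224 in pairs 1 to 4. The highest correlation with a cow of another pair was 0.208, 0.449, 0.0771 and 0.576. Pairs 1 and 4 thus showed no deviation specific to the pair, and a fit of unpaired cows was run as an alternative.

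The lists, the tests and the rule for named genes were fixed before the data were examined. The rule took the 10 genes higher and the 10 lower in high-yield cows that passed the test with the same sign in 4 pairs, filled by smallest unadjusted p where fewer passed. It added every measured milk protein gene, the 4 members of smallest p of every other list, and the 5 genes of smallest p for the difference between lactations. It named 152 genes, of which 0 passed the test over all genes with limma, where 677 of all genes had an unadjusted p under 0.05. The steps were tested on simulated data. For the yield comparison, with the real spread of the 29867 probes, 0 of 100 probes changed by 1 on the log2 scale and 66 of 100 changed by 2 were called, with 3 false calls. With 0.1 of that spread, 99 and 100 of 100 were called. With the real spread of the 12436 genes, drawn independently of each other, 31 of 32 lists moved by 1 were called. Members of some real lists were correlated, at an estimated 0.992 for milk proteins and 0.699 for oxidative phosphorylation. The simulation therefore does not show how the list test behaves with correlated members.

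The alternatives were other starting values (no background subtraction, an offset of 16, the processed signals, the authors' table), median centring, scaling between arrays, other filters on dim probes, keeping outlier spots, and a trend and robust variance model. Others were the 8 arrays with the pair as a random block, unpaired cows, a slide term and each lactation alone. Each pair left out in turn, each dye orientation alone, and the median over a gene's probes were run too. In the fits of a lactation alone, the mean was that of its pairs, while the variance came from the pairs of both lactations. The saddle-point fit and a fit of unpaired cows without the low-yield cow of pair 1 were chosen after the data were seen. The scanner's flags for saturation were read and excluded nothing.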

Results

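Gene expression was measured in the mammary gland of 8 lactating cows of the Holstein Friesian dairy breed, 4 with a high milk yield, averaging 11097 kg per lactation, and 4 with a low yield, averaging 6956 kg. Each of 4 pairs joined 1 high-yield and 1 low-yield cow of the same lactation on 2 arrays with exchanged dyes, and 2 pairs were in lactation II and 2 in lactation IV. Between 22027 and 42482 of 43653 probes per channel were well above background. After filtering, 29867 probes and 12436 named genes were tested. Values are log2 ratios of high-yield over low-yield cow, given as the mean and SD of the 4 pairs, so that 1 stands for a doubling.

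The dye-swapped arrays of a pair correlated across probes at 0.753 in pair 1, 0.294 in pair 2, 0.668 in pair 3 and 0.260 in pair 4, where probes are not independent replicates. Between pairs the correlation was 0.000111 for pairs 1 and 2, -0.336 for pairs 1 and 4, -0.244 for pairs 1 and 3, 0.246 for pairs 2 and 3, 0.111 for pairs 2 and 4 and 0.314 for pairs 3 and 4. Pair 1 thus differed in the opposite sense from the pairs of lactation IV.

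The first comparison asked which genes of the gland differ between cows of high and low milk yield. FBP2, a fructose bisphosphatase of gluconeogenesis, had a 5.75-fold higher signal in high-yield cows, a log2 ratio of 2.52 ± 0.72 (SD, n = 4 pairs). Haemoglobin alpha (HBA), the oxygen carrier of red blood cells, stood at 2.15 ± 0.98, and SCNN1G, a subunit of the epithelial sodium channel, at 1.73 ± 0.50. In the other direction stood B2M, the light chain of MHC class I molecules, at -1.34 ± 0.39, and GHR, the growth hormone receptor, at -0.58 ± 0.07. Each of these 5 genes had the same sign in 4 of 4 pairs, yet none passed the test over all genes (limma, adjusted p = 0.787 for each).

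Other genes with a higher signal in the high-yield cow of 4 of 4 pairs were TMEM201 (2.32 ± 0.88), a protein of the inner nuclear membrane, NUPR1 (1.44 ± 0.55), a stress-induced nuclear protein, and DEPP1 (1.40 ± 0.56), a target of FOXO transcription factors. ZMIZ1 (1.37 ± 0.58), a transcriptional co-regulator, NTN3 (1.15 ± 0.22), a netrin, and NATD1 (0.83 ± 0.06) did so too. Lower in 4 of 4 pairs were APP (-1.17 ± 0.35), the amyloid precursor protein, TUBA1B (-1.17 ± 0.43), an alpha tubulin, HYCC2 (-0.94 ± 0.31), the histone H3-5 (-0.87 ± 0.34) and HNRNPAB (-0.85 ± 0.34), an RNA-binding protein. So were AFF3 (-0.82 ± 0.32), C13H10orf18 (-0.71 ± 0.06), whose other probe had the opposite sign, and ATP6AP2 (-0.65 ± 0.17), a subunit that associates with the vacuolar proton pump. Of these 14 genes, 0 passed the limma test over all genes (adjusted p = 0.787 for each), where 677 genes had an unadjusted p under 0.05.

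**Figure D1:**
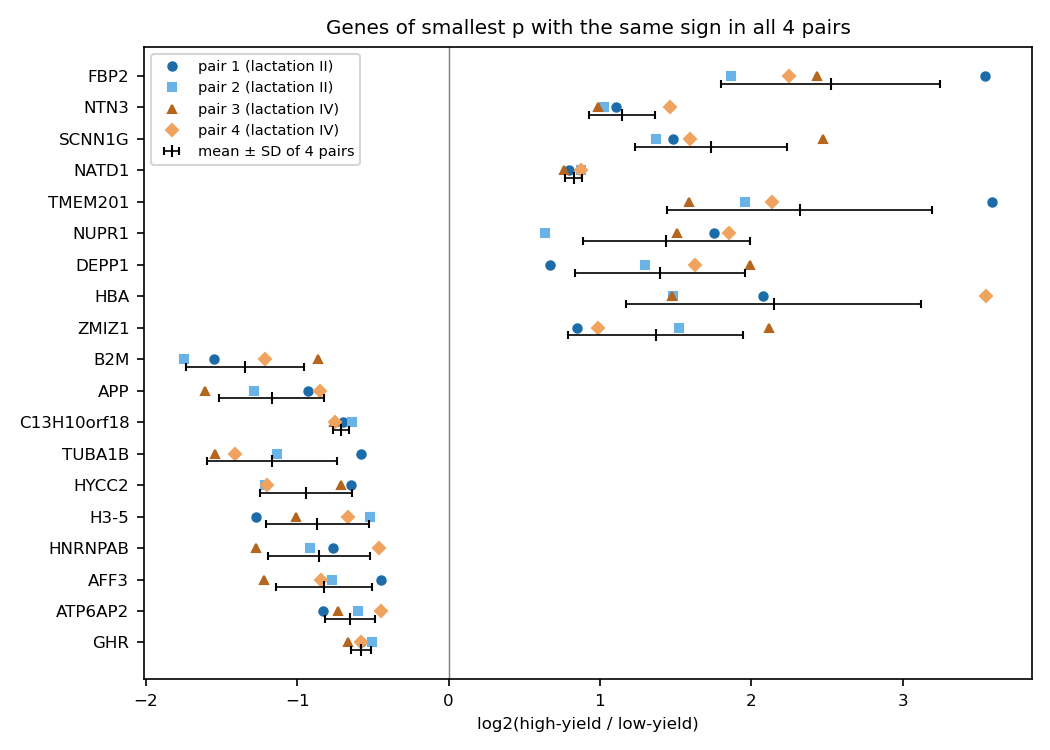
Log2 ratio of high-yield over low-yield cow for the 9 higher and 10 lower genes of smallest p with the same sign in all pairs; points are the 4 cow pairs and bars the mean with its SD. FBP2 has the largest mean, 2.52, and B2M the lowest, -1.34.

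The probe of FBP2 lies on chromosome 8 at 85344924 to 85344983 of build HGSC Btau_3.1, that of HBA on chromosome 25 at 673407 to 673466, and that of SCNN1G on chromosome 25 at 22173772 to 22173831. NUPR1 was measured on chromosome 25 at 27895227 to 27895286 and DEPP1 on chromosome 28 at 44791384 to 44791443. B2M was measured on chromosome 10 at 106114776 to 106114835, APP on chromosome 1 at 9913799 to 9913858, TUBA1B on chromosome 5 at 33740923 to 33740982 and GHR on chromosome 20 at 33896819 to 33896878.

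Across all genes the limma test called 0 of 12436 genes and 0 of 29867 probes at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 677 genes (351 higher and 326 lower in high-yield cows), where chance gives 622, and 1926 probes (751 higher, 1175 lower), where chance gives 1493. The same sign in 4 pairs was found for 2177 genes, or 17.5%, of which 1212 were higher and 965 lower, where chance gives 12.5%. Within lactation II, on slide 1, 0 genes passed (680 at an unadjusted p under 0.05), and within lactation IV, on slide 2, 0 passed (1015). With a slide term 0 passed (709), all with limma. The tests within a lactation took their variance from the pairs of both lactations.

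The milk protein genes set pair 1 apart from the other pairs. LALBA, which encodes alpha-lactalbumin, the regulatory subunit of lactose synthase, was at 9.86 in pair 1 but at -1.16 in pair 2 and -1.86 in pair 4, with pair 3 also below 0. The caseins followed the same pattern, CSN1S1 with 8.58, -1.70, -0.94 and -1.07, CSN1S2 with 6.79, -1.80, -0.86 and -1.04, CSN2 with 5.45, -1.42, -0.03 and -0.62, and CSN3 with 7.10, -1.07, -1.32 and -1.40. PAEP, the whey protein beta-lactoglobulin, was at 5.72 in pair 1 and at -0.23, -0.03 and -0.89 in the others. GLYCAM1, a mucin of the milk fat globule membrane, was at 9.45, -0.33, 0.63 and 0.25. Their means of 0.77 to 2.50 were smaller than their SDs of 3.07 to 5.61, and adjusted p lay between 0.788 and 0.910.

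In levels, LALBA stood at 9.76 (log2 intensity) in the low-yield cow of pair 1, at 17.91 to 18.05 in the other low-yield cows and at 19.63, 16.89, 16.91 and 16.15 in the high-yield cows of pairs 1 to 4. CSN1S1 stood at 11.01 in the low-yield cow of pair 1 and at 19.59 in the high-yield cow of that pair. The luminal keratins KRT8 and KRT18 went the other way in that cow, at 15.34 and 13.79, above each of the other 7 cows. KRT19, at 15.05, was below the 4 high-yield cows there but above the other low-yield cows. ELF5, a transcription factor of secretory epithelium, was lowest there, at 12.69. LALBA was measured on chromosome 5 at 34388762 to 34388821, CSN1S1 on chromosome 6 at 88307281 to 88307925, CSN2 at 88329295 to 88329354, CSN1S2 at 88421964 to 88422023 and CSN3 at 88534334 to 88534393 of the same chromosome. The probes of the 4 casein genes thus lie on the same stretch of chromosome 6.

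**Figure D2:**
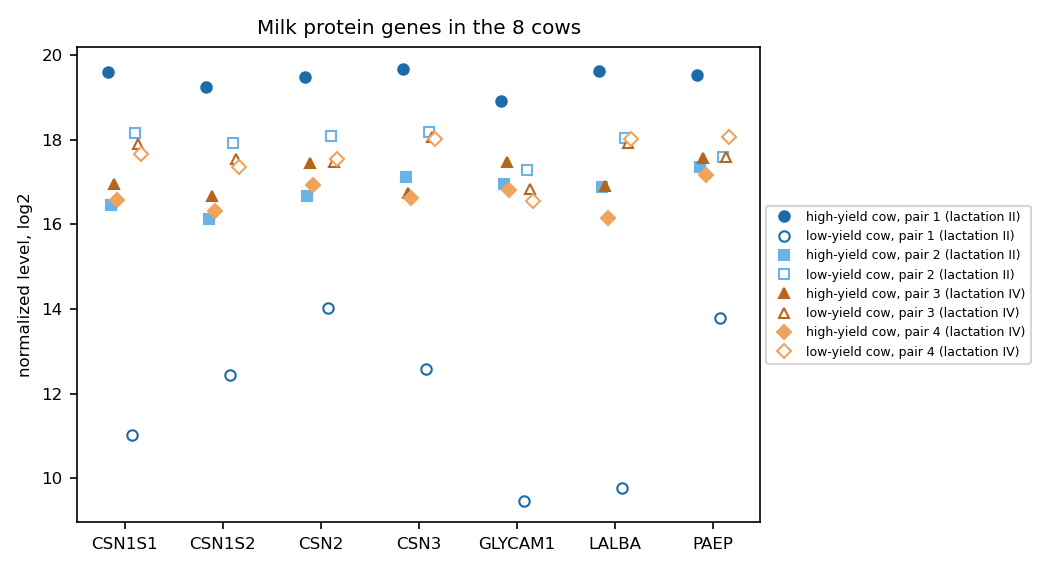
Normalised level (log2 intensity), rebuilt from mean intensity and ratio, of the milk protein genes in each of the 8 cows, by yield and pair. The low-yield cow of pair 1 stands apart, with LALBA at 9.76 against 16.15 to 19.63 in the other cows. The high-yield cow of the same pair is the highest for each gene.

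Of the 32 lists, 3 passed the camera test for yield. Erythrocyte genes rose in high-yield cows (median 0.84, 7 genes, adjusted p = 0.00859), with 6 of 7 members higher and 5 of them higher in 4 of 4 pairs. The list did not pass with an estimated correlation (adjusted p = 0.962 with an estimated correlation). Among these, beside HBA, were HBM (1.01 ± 0.71) and HBB (0.93 ± 1.12), further globins, and AHSP (0.51 ± 0.47), the chaperone of alpha haemoglobin. HBM and HBB were dim in the low-yield cows, at 5.93 to 6.59 and 6.01 to 6.41 (log2 intensity), so their ratios are weak evidence. HBA passed when adjusted over the list alone (adjusted p = 0.0173) and was the single member to do so in any list, while 0 members of any list passed over all genes.

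Genes of endoplasmic reticulum stress and folding fell (median -0.32, 19 genes, adjusted p = 0.00456), with 12 of 19 members lower and 6 of them lower in 4 of 4 pairs. This call was lost with an estimated correlation (adjusted p = 0.962 with an estimated correlation). Among the lower members were the chaperones HSP90B1 (-0.50 ± 0.22) and CANX (-0.55 ± 0.28), the disulphide isomerase PDIA4 (-0.43 ± 0.23) and the stress sensor kinase EIF2AK3 (-0.56 ± 0.45). T and NK cell genes fell (median -0.26, 16 genes, adjusted p = 0.0339), with 14 of 16 members lower, among them CD2 (-0.57 ± 0.65), CD3E (-0.57 ± 0.73) and CD8B (-0.27 ± 0.36). This call was lost as well (adjusted p = 0.962 with an estimated correlation).

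Of the 3 list calls, that of erythrocyte genes held with each pair left out in turn (adjusted p from 0.00273 to 0.0196), and the others did not. Without pair 3 the erythrocyte median fell to 0.34. With a slide term each of the 3 still passed (adjusted p = 0.011 for each). The median of the endoplasmic reticulum list was -0.12 in lactation II (adjusted p = 0.685) and -0.58 in lactation IV (adjusted p = 7.10e-07). That of T and NK cells was -0.51 (adjusted p = 6.68e-05) and 0.10 (adjusted p = 0.767). For erythrocytes it was 0.41 (adjusted p = 0.137) and 1.13 (adjusted p = 0.00324). These p-values rest on the variance of the pairs of both lactations, not on 1 lactation alone. The endoplasmic reticulum list did not pass without pair 4 (adjusted p = 0.170), the T and NK list without pair 1 (0.665), pair 2 (0.0503) or pair 4 (0.0572) or with probes above background in all channels (0.172), and the erythrocyte list in unpaired cows without the low-yield cow of pair 1 (0.128), a fit chosen after the data were seen. With the high-yield cow in Cy5 alone none of the 3 passed (adjusted p = 0.658 for the endoplasmic reticulum list, whose median was then 0.03, 0.312 for T and NK cells and 0.140 for erythrocytes), and with it in Cy3 alone the lists of T and NK cells and erythrocytes did not (0.131 for both). Without pair 1, 10 lists passed in place of 3, among them milk proteins with a median of -1.23 (adjusted p = 6.03e-05), the opposite sign of the median over 4 pairs. All adjusted p-values of this paragraph use the preset correlation of 0.01. None of these fits was run with an estimated correlation, so small values among them are weak evidence.

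Lists of milk synthesis did not pass over the 4 pairs. The milk proteins had a median of 1.14 (7 genes, adjusted p = 0.470), milk fat globule secretion 0.33 (12 genes, 0.521) and lactose synthesis and glucose uptake 0.20 (15 genes, 0.526), with GALT, a galactose enzyme, at 0.26 ± 0.15. Milk fat synthesis had a median of 0.06 (33 genes, 0.839), where mean and median were above 0 and the test pointed down, and cholesterol synthesis had -0.21 (20 genes, 0.833). Without pair 1 both lists passed, at medians of -0.41 (adjusted p = 1.12e-07) and -0.83 (adjusted p = 4.29e-07). INSIG2, a brake on sterol synthesis, was at -0.46 ± 0.17, and MVK, the mevalonate kinase, at 0.49 ± 0.29. Amino acid transport had a median of 0.09 (14 genes, 0.782), and calcium, phosphate and zinc transport -0.19 (14 genes, 0.452), with the phosphate transporter SLC20A1 at -0.63 ± 0.19, although 1 of its probes had the opposite sign. Oxidative phosphorylation had a median of 0.08 (31 genes, 0.943).

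Among the signalling lists, genes of prolactin, growth hormone and STAT signalling had a median of -0.22 (15 genes, adjusted p = 0.126). GHR, the kinase JAK2 (-0.64 ± 0.31) and the prolactin receptor PRLR (-0.88 ± 0.70) were lower in 4 of 4 pairs, while STAT5A, the transcription factor downstream of them, was at 0.57 ± 0.67 with 2 of its 3 probes of the opposite sign. With a slide term this list passed (camera, adjusted p = 0.0427), as it did without pair 1 (0.0196). Over the 4 pairs its adjusted p was 0.962 with an estimated correlation. Insulin, IGF and mTOR signalling had a median of -0.07 (20 genes, 0.520), a test pointing down and a mean just above 0. Its member EIF4EBP1, which holds back the cap-binding factor EIF4E, was at 1.04 ± 0.59, and EIF4E itself at -0.64 ± 0.48. Steroid and thyroid hormone receptors had a median of 0.02 (9 genes, 0.670) with a test pointing down.

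Among the lists of defence and remodelling, acute phase and antimicrobial genes had a median of 0.44 (24 genes, adjusted p = 0.367), with complement C3 at 1.15 ± 0.64, and without pair 4 the median of the list was -0.03. Involution, apoptosis and remodelling genes had a median of 0.09 (24 genes, 0.670), cytokines, chemokines and Toll-like receptors 0.01 (24 genes, 0.943) with a test pointing down, interferon response -0.07 (21 genes, 0.521), and MHC class II -0.10 (8 genes, 0.839), where the mean was above 0. BOLA-DQA2, a class II chain, was at 2.16 ± 1.26 and missed the threshold adjusted over the list alone (0.0532). It was dim in the low-yield cows of pairs 1 and 2, at 5.19 and 6.06 (log2 intensity), so its ratios there are weak evidence. Cell proliferation had a median of -0.09 (20 genes, 0.126) with 17 of 20 members lower, PCNA, the sliding clamp of DNA replication, at -0.55 ± 0.16. Immediate early and heat shock genes had a median of -0.09 (22 genes, 0.470) and tight junctions -0.01 (13 genes, 0.592), with occludin (OCLN) at -0.50 ± 0.14 and TJP1 at -0.35 ± 0.10, although 1 of the 3 probes of TJP1 had the opposite sign.

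Of the other cell type lists, luminal epithelium had a median of 0.01 (9 genes, adjusted p = 0.996), although KRT19 was at 1.28 ± 0.79. Myoepithelium had 0.09 (10 genes, 0.670), adipocytes 0.13 (9 genes, 0.521), fibroblasts 0.41 (11 genes, 0.521), endothelium 0.30 (9 genes, 0.521), and B and plasma cells 0.15 (10 genes, 0.526). Neutrophils had a median of 0.11 (12 genes, 0.521), skeletal muscle 0.17 (8 genes, 0.470) and lymph node 0.30 (6 genes, 0.943). Macrophages and dendritic cells had 0.003 (14 genes, 0.839), where the mean and the test were below 0. Single pairs carried some of these medians. Without pair 4 that of fibroblasts was 0.02 and that of lymph node -0.23, and without pair 1 that of endothelium was -0.05.

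**Figure D3:**
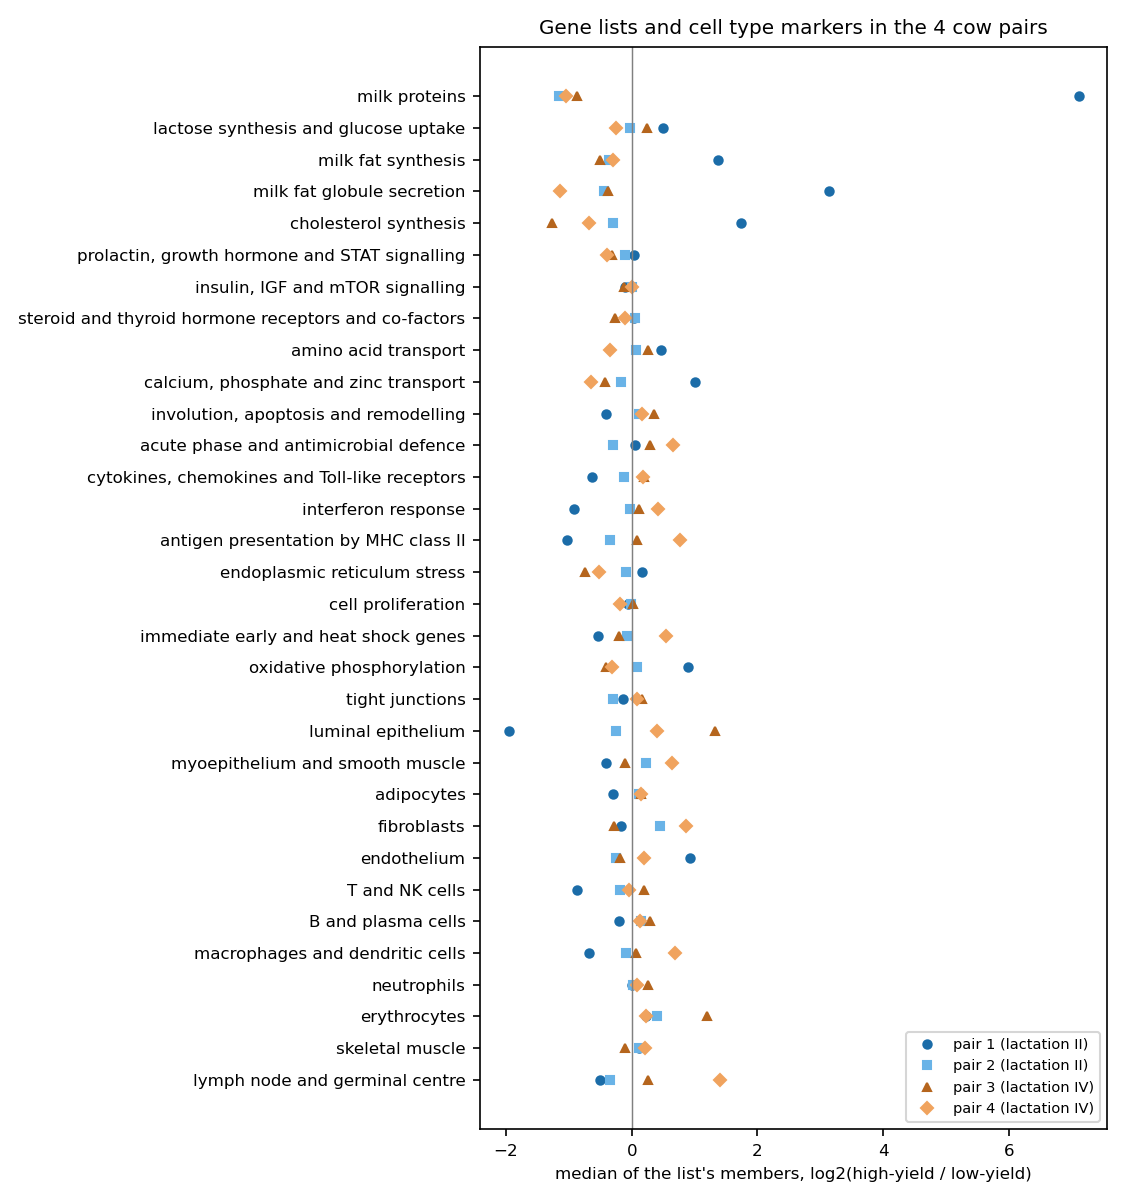
Median log2 ratio of high-yield over low-yield cow of each gene list and cell type list in each of the 4 pairs. The milk protein list is at 7.10 in pair 1 and at -1.16, -0.86 and -1.04 in pairs 2, 3 and 4.

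The second comparison asked whether the effect of yield differed between lactation IV and lactation II. Genes of oxidative phosphorylation had a lower ratio in lactation IV (median difference -0.86, 30 of 31 members lower, adjusted p = 5.59e-08), as had those of cholesterol synthesis (-1.89, 18 of 20, adjusted p = 4.73e-06) and milk fat synthesis (-1.29, 27 of 33, adjusted p = 0.00115). None of these 3 calls held with an estimated correlation (adjusted p = 0.601 with an estimated correlation for each). Cholesterol genes had a median of 0.71 in lactation II and -0.91 in lactation IV, and milk fat genes of 0.58 and -0.48, but the values above 0 came from pair 1, since pair 2 of the same lactation stood at -0.30 and -0.37. Interferon response genes went the other way (0.84, 20 of 21 members higher, adjusted p = 0.000137). This call was lost too (adjusted p = 0.601 with an estimated correlation).

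In all, 16 of the 32 lists passed for the difference (n = 2 pairs in each lactation). Lower in lactation IV were also milk proteins (-4.11, adjusted p = 0.0205), milk fat globule secretion (-2.78, 0.0307), calcium, phosphate and zinc transport (-0.76, 0.00664) and endoplasmic reticulum stress (-0.50, 18 of 19 members, 0.000109). Higher were cytokines, chemokines and Toll-like receptors (0.76, 0.00103), lymph node (1.29, 0.00317), T and NK cells (0.82, 0.00355), luminal epithelium (1.68, 0.00361), involution (0.45, 0.0205), acute phase genes (1.02, 0.0205), MHC class II (0.97, 0.0205), and macrophages and dendritic cells (0.65, 0.0349). The adjusted p = 0.601 with an estimated correlation for each of them.

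The lists that missed the threshold for the difference were tight junctions (0.35, adjusted p = 0.0745), erythrocytes (0.57, 0.0745), immediate early genes (0.54, 0.0754), B and plasma cells (0.26, 0.101), amino acid transport (-0.33, 0.113), endothelium (-0.31, 0.153), prolactin signalling (-0.11, 0.221), neutrophils (0.23, 0.288), myoepithelium (0.24, 0.301) and steroid receptors (-0.22, 0.342). The lactose list had a median difference of 0.03 with a test pointing down (0.550), and adipocytes had 0.24 (0.722), insulin signalling -0.02 with a test pointing up (0.754), fibroblasts 0.27 (0.754), proliferation 0.01 (0.774) and skeletal muscle -0.04 (0.947). By fry, 2 lists passed, tight junctions and erythrocytes (adjusted p = 0.0448 for both).

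SAA3, a serum amyloid gene that encodes an acute phase protein, had the smallest p of single genes. It was at -3.49 and -3.33 in the pairs of lactation II and at 2.60 and 3.14 in those of lactation IV, a difference of 6.28 (limma, adjusted p = 0.148). SAA2 was at -3.27 and -2.97 and then at 2.18 and 3.15 (adjusted p = 0.260), although 1 of its 3 probes lay between 0.21 and 0.37 in each pair, and C4BPA, a regulator of complement, at -1.14 and -0.84 and then at 3.53 and 3.05 (adjusted p = 0.260). Opposite to them, PSPH, the last enzyme of serine synthesis, was at 2.09 and 1.61 and then at -3.49 and -3.85, and NXPH3, a neurexophilin, at 3.18 and 3.01 and then at -1.75 and -1.68 (adjusted p = 0.148 for both). Over all genes limma called 0 of 12436 genes for the difference (985 at an unadjusted p under 0.05) and 0 of 29867 probes (2287).

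Adjusted over the list alone, 8 acute phase members passed for the difference, and the genes named from here on were chosen after their values were seen. They were SAA3, SAA2, CHI3L1 (6.05), LCN2 (4.53) and the complement factor CFB (4.22), higher in lactation IV, and PTX3 (-5.60), CATHL5 (-4.65) and CATHL2 (-2.59), lower. Of endoplasmic reticulum stress genes 4 passed, the transcription factors ATF4 (-2.20) and DDIT3 (-1.60), TRIB3 (-5.53) and the asparagine synthetase ASNS (-3.47). Of amino acid transporters 5 passed, SLC1A5 (-4.52), SLC7A5 (-3.98), SLC1A4 (-3.66), SLC38A2 (-1.42) and SLC1A1 (2.84). Of cytokine genes 2 passed, IL1RN (2.71) and CCL28 (2.54), and 1 each passed in 4 more lists, SOCS1 (-2.44), ATP2B2 (-2.05), BOLA-DQA2 (-2.12) and ELF3 (3.03). None of the 23 passed over all genes, and for LCN2 and BOLA-DQA2 the other probe differed in the opposite direction (-1.71 and 1.06).

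Each lactation lay on a slide of its own, so no value of the difference within a slide or with the slide as a block exists. In unpaired cows 13 lists passed for the difference in place of 16, with acute phase genes (adjusted p = 0.0858), MHC class II (0.0858) and macrophages and dendritic cells (0.310) lost. With the low-yield cow of pair 1 left out as well, chosen after the data were seen, 9 passed, 7 of them among the 16 with the same direction, and those also lost were milk fat synthesis (0.0797), T and NK cells (0.0797), interferon response (0.0845), milk proteins (0.135), involution (0.148) and milk fat globule secretion (0.233). Without pair 1, 13 lists passed, 12 of them among the 16 with the same direction. Without pair 4, 8 lists passed, and without pair 2, 217 genes passed in place of 0. Such fits leave 1 pair in a lactation, which is assumed to vary like the pairs of the other.

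**Figure D4:**
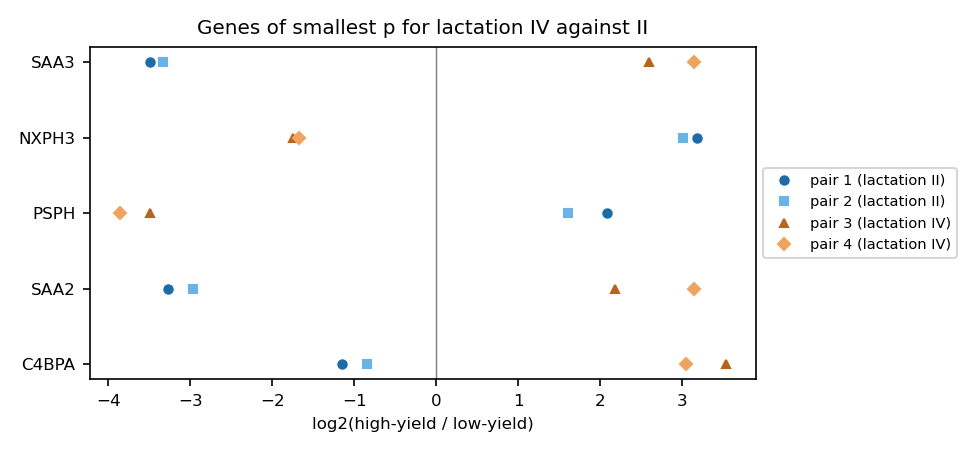
Log2 ratio of high-yield over low-yield cow in each pair for the 5 genes of smallest p for the difference between lactations. SAA3 is at -3.49 and -3.33 in lactation II and at 2.60 and 3.14 in lactation IV.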

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

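The tests of explanations in this part were chosen after the results were seen, except for the count over other groupings of the pairs.

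In 20 of 184 sets of 4 pair values, 1 pair stood far from the others by Dixon's criterion, where chance gives 9.2 for independent sets. These sets were not independent, since milk genes moved together and lists repeat their members. The genes were also selected, so the excess is no measure against chance. Of the 20, 14 had pair 1 as the outlying value, 0 pair 2, 5 pair 3 and 1 pair 4. In pair 1 these were the milk genes LALBA (9.86), GLYCAM1 (9.45), CSN1S1 (8.58), CSN3 (7.10), CSN1S2 (6.79) and PAEP (5.72), the mucin MUC1 (6.98), the lipid droplet protein PLIN2 (3.03), and the lists of milk proteins (median 7.10) and milk fat synthesis (median 1.37). Pair 1 also stood apart for the fatty acid elongase ELOVL6 (-1.08, with 1 of 3 probes near 0), the chemokine CXCL3 (1.85), the lipase LIPE (0.64) and the adipocyte list (median -0.30). In pair 3 they were HSD11B1 (-0.27), BAK1 (0.72, with its other probe at -0.05), PAX5 (0.87), CD79A (1.98) and MYH2 (-0.53), and in pair 4 HSD11B2 (0.56).

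The milk genes of pair 1 were weighed first. A failed array or dye is argued against, since 7 of 7 milk protein genes were over 2 on the log2 scale on both dye-swapped arrays of that pair. Fewer epithelial cells in the piece of the low-yield cow are argued against too. The luminal epithelium list had a median of -1.96 in that pair, with 2 of 9 members above 0. Thus 7 of 9 epithelial markers were higher in the low-yield cow, KRT19 and ELF5 being the exceptions. The list does not separate secretory from other epithelium, and ELF5 was lowest in that cow, at 12.69. Fewer secretory cells are therefore not excluded. Yield class as the cause is argued against by pairs 2 to 4, where 2 of 21 milk protein values were above 0. A single wrong label, or a gland of that cow in another state than full lactation, may be a cause and was not tested.

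In 16 lists the effect of yield differed between lactations by the test of the difference itself, lower in lactation IV in 7 and higher in 9, but none passed with an estimated correlation (adjusted p = 0.601 with an estimated correlation for each). The median differences were -4.11 for milk proteins, -2.78 for milk fat globule secretion, -1.89 for cholesterol synthesis, -1.29 for milk fat synthesis, -0.86 for oxidative phosphorylation, -0.76 for calcium, phosphate and zinc transport and -0.50 for endoplasmic reticulum stress. They were 1.68 for luminal epithelium, 1.29 for lymph node, 1.02 for acute phase genes, 0.97 for MHC class II, 0.84 for interferon response, 0.82 for T and NK cells, 0.76 for cytokines, 0.65 for macrophages and dendritic cells and 0.45 for involution.

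These differences between lactations were weighed next, and in milk proteins, milk fat, milk fat globule secretion and cholesterol the median was above 0 in pair 1 and below 0 in pair 2 as in pairs 3 and 4. The low-yield cow of pair 1 cannot alone have given the differences that remain without it. For how many of the 16 lists that cow alone is the cause cannot be told. In unpaired cows without that cow, 7 of the 16 passed with the same direction. This lies between the bounds set for and against that cause, at most 3 and at least 12. The fit also leaves 1 low-yield cow in lactation II. The fit without pair 1 leaves 1 pair in lactation II and cannot decide it. The low-yield cow of pair 1 stays open for the lists of milk proteins, milk fat, fat globule secretion and involution, of which 0 passed in either fit, as fewer samples could also give. A slide or scan effect cannot be told apart from the number of the lactation, since 0 slides hold pairs of both lactations, and both stay open, as do other differences between single cows. Of the 3 ways to set 2 pairs against 2, 1 gave as many lists, the real one with 16 against at most 12 in the others, and 3 ways are too few for a share under 0.05.

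In pairs 2 to 4 genes of milk fat and cholesterol synthesis were lower in the high-yield cow. The medians were -0.37, -0.50 and -0.29 for milk fat and -0.30, -1.26 and -0.67 for cholesterol, against 1.37 and 1.74 in pair 1. Under 7 other starting values or normalizations, 41 of 42 such medians stayed below 0, so the sign hardly depended on the background correction. Normalization as the cause is not decided by this count. Several of these settings changed the background step and kept the within-array loess, and scaling between arrays can hardly turn a sign. Median centring replaced the loess, but it moved the median of all genes from 0.03 to -0.15. Fewer epithelial cells in the pieces of the high-yield cows cannot be told apart from lower expression per cell, since the luminal epithelium median was above 0 in 2 of 3 pairs. Yield, the day of lactation and feeding may each be involved, and none was tested.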

How the results depend on the processing

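The saddle-point background fit and the unpaired fit without the low-yield cow of pair 1 were chosen after the results were seen. No alternative called a probe or gene for yield at an adjusted p under 0.05 (1926 probes at an unadjusted p under 0.05 and 294 under 0.01). The 20 genes of smallest p kept their sign under other starting values, normalizations, filters and dye orientations, as far as measured there (19 of them with the filter on all 16 channels and 19 with the high-yield cow in Cy5 alone); leaving out pairs could not turn it, since they were chosen for 1 sign in all pairs. Of 3627 values of named genes under alternatives, 115 had the other sign, and 0 were called. Of 736 list values, 592 kept direction and side of the threshold, 32 newly passed, 14 no longer passed, 85 moved and 13 reversed. Median centring moved the median of all genes from 0.03 to -0.15 and the share of higher probes among those at an unadjusted p under 0.05 from 39.0% to 10.07%, relative to which its values must be read.

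For yield, median centring called 6 lists in place of 3, and leaving out pairs in turn 2 to 10. Lactation II alone gave 12 and lactation IV alone 14, with a variance taken from the pairs of both lactations. The arrays with the high-yield cow in Cy5 gave 0 and those with it in Cy3 1. The unpaired fit without the low-yield cow of pair 1 called 5, camera with an estimated correlation 0 and fry 0. For the difference between lactations, the 8 arrays with the pair as a random block called 32 probes and 25 genes in place of 0 and 0, and median centring called 7 genes. Leaving out pairs in turn gave 0 to 179 probes and 0 to 217 genes, the highest without pair 2, and 8 to 22 lists in place of 16, the lowest without pair 4 and the highest without pair 3. The unpaired fit without that cow gave 9 lists, an estimated correlation 0 and fry 2. The cause of these changes was not tested. Where pairs, cows or arrays were left out, there were also fewer samples. The random block was not run for lists, and the estimated correlation and fry were run for the main fits alone.

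Leaving out pairs in turn moved the median of milk proteins between -1.23 and 1.82, of milk fat globule secretion between -0.71 and 0.69 and of oxidative phosphorylation between -0.19 and 0.23, each reversed without pair 1. The following holds for lists that passed in a lactation alone or over the 4 pairs. In lactation II alone test and median reversed for cholesterol (0.71), luminal epithelium (-1.10) and lymph node (-0.39). For milk fat (0.58) and endoplasmic reticulum stress (-0.12) the test changed direction while the median kept its sign. In lactation IV alone the test for cytokines (0.29) changed direction while the median kept its sign. Test and median reversed there for interferon response (0.30), MHC class II (0.44), oxidative phosphorylation (-0.34) and T and NK cells (0.10). Medians of some lists that passed neither over the 4 pairs nor in lactation IV alone also changed sign in lactation IV alone. Among them were milk proteins (1.14 to -0.95) and milk fat globule secretion (0.33 to -0.83), which passed in lactation II alone.

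With no replicate block, that is without the pairing, 0 probes and 0 genes were called for yield and 0 for the difference. The lists were 2 in place of 3, T and NK cells being lost (adjusted p = 0.109), and 13 in place of 16. No other call for yield changed without the pairing. Signal over background limits the dimmer probes, and a filter on all 16 channels kept 21038 of 29867 probes.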

Other observations

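The counts over other splits of the samples were fixed before they were run, and all other values in this part were looked at after the results were seen.

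The low-yield cow of pair 1 combined low milk transcripts with strong signals of some keratins. Its KRT15 level was 16.65 (log2 intensity), with KRT8 at 15.34 and KRT18 at 13.79, while LALBA was at 9.76 and CSN1S1 at 11.01. Its KRT19 level of 15.05 was below the 4 high-yield cows but above the other low-yield cows. In the same pair the interferon list had a median of -0.92 and T and NK cells one of -0.87, so that these transcripts were also higher in the low-yield cow.

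Some members of the lists of endoplasmic reticulum stress and amino acid transport were above 0 in both pairs of lactation II and below 0 in both pairs of lactation IV. TRIB3 was at 4.13, 1.94, -2.18 and -2.81 in pairs 1 to 4, ASNS at 2.57, 1.28, -1.32 and -1.77 and the transporter SLC7A5 at 2.95, 0.09, -2.21 and -2.72. The transcription factor ATF4 was at 1.48, 0.67, -1.49 and -0.77. The transporter SLC38A2 did not show this, at 0.10, -0.14, -1.61 and -1.28. These genes were picked after their values were seen.

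For yield with the pairs kept, the 8 ways to turn the signs of the 4 pairs allow no share under 0.125. The real count of probes at an unadjusted p under 0.05 was 1926 and the highest other 3356, with 3 of the 8 ways as large. For genes it was 677 against 1558, with 3 ways as large, and for lists 3 against 16, with 8 ways as large.

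With cows unpaired, there were 35 splits into 4 and 4, and chance could not be excluded for any of the counts. The real split gave 1364 probes at an unadjusted p under 0.05, the highest other 6780, and 12 of the 35 splits gave as many. It gave 533 genes against 2762, with 13 splits as large, and 2 lists against 15, with 33 splits as large. Among the 8 splits that part all 4 pairs, the highest other counts were 2245 probes and 14 lists. The split with 6780 probes set the cows of pairs 1 and 4 against those of pairs 2 and 3, which follows neither yield nor lactation nor slide. The other splits that keep pairs whole gave 859 probes, and 1218 probes and 4 lists for the split by lactation and slide, while a split that parts 2 pairs gave 5548. The cows of a pair shared their arrays, so splits that keep pairs whole set arrays against arrays, while the real split lies within arrays. Counts of such splits cannot be set directly against the real one, and no test addressed what gave the higher counts.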
